A study of Mus musculus with 8 samples.

How the data were processed

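Gene expression was measured in mouse embryonic stem cells on 8 single-colour Illumina MouseRef-8 v2.0 bead arrays, a platform on which biotin-labelled RNA binds bead-borne probes and each probe yields a brightness. The labels gave 4 groups of 2 arrays, named wild type (floxed cells that keep both genes), Lin28a loss, Lin28b loss and loss of both genes (double loss). Replicates were numbered 1 and 2 in accession order, which only names an array. Outside wild type, replicate 1 carries a title number of 16 to 18 and replicate 2 one of 20 to 22. Nothing in the labels said that the 2 arrays of a group came from separate cultures or clones, so p-values measure the spread between these arrays, which may be technical. Array titles began with "b" for wild type and Lin28b loss and with "ab" for Lin28a loss and double loss. They held "flox" for wild type and Lin28a loss and "null" for the other groups, and each carried a number (7 and 13 in wild type, 16 to 18 and 20 to 22 in the other groups).

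The deposited value table held normalized intensities per probe and array on a linear scale, which could fall below 0. A further deposited table held, per the file headers, intensities without normalization as the lowest and highest signal of each group, with 1 detection p per probe and group and none per array. GenomeStudio was named in the submitters' processing notes, and its version and the normalization method were not given in the sources used here. Set against the unnormalized signals, each array's deposited intensities followed a straight line, with slopes from 0.65 (wild type replicate 1) to 1.45 (labelled Lin28a loss replicate 2) and intercepts from -1.3 (Lin28b loss replicate 2) to 21.8 (wild type replicate 2). The median deposited intensity was 37.4 and 42.8 in wild type, 35.4 and 39.2 in labelled Lin28a loss, 37.0 and 29.5 in Lin28b loss and 36.5 and 35.0 in double loss. Over the 2383 probes with a detection p above 0.5 in all 4 groups, the median was 11.3 and 15.6 in wild type, 1.8 and 4.7 in labelled Lin28a loss, 5.9 and -7.7 in Lin28b loss and 5.2 and 3.5 in double loss, so background was not brought to one level. How the scaling was chosen stays unknown. The number of arrays limits the precision of every value.

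The plan fixed before the data were examined called for background correction and normalization with neqc, which needs control probes or per-array detection p-values. These were not among the tables used here, so the deposited normalized intensities were taken as they stood and transformed to log2 of the intensity plus 16, with values below 0 set to 0. Differences on this scale understate the change of dim genes. A probe was kept when its group detection p was below 0.05 in at least 1 group, which left 15694 of 25697 probes (61.1%). Probes were named through gene identifiers (16938 probes), unversioned accessions (7420), symbols (465) or unique synonyms (553) of a RefSeq gene table for the GRCm38.p6 assembly, and 321 kept the name in the file. That table served only for names and for which genes neighbour each other. The brightest kept probe stood for each gene, which gave 11377 genes, and named genes whose other probes moved apart are pointed out.

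Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and 4.99 prior degrees of freedom, and 7 contrasts were tested with moderated statistics. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a contrast are called. On simulated data for double loss against wild type over 11377 genes, 19.1% of 68 genes changed by a log2 of 1 were recovered, 92.4% of 66 changed by 2, and all 66 changed by 3, with 12 false calls. Of 29 gene lists fixed before the data were examined, the 28 with at least 4 measured genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. The tests were repeated with an estimated correlation and with fry, which asks whether a list moves one way on balance. Across the 7 contrasts 67 of 196 pairs of list and contrast passed with the preset correlation, and 0 passed with an estimated correlation or with fry, where the lowest adjusted p was 0.178 and 0.0587.

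Where a group's detection p was 0.05 or above, each of its arrays was taken as no lower than the lowest group mean among probes detected in it, and the brighter group over the mean of these levels is given as "at least N-fold". Genes named in each comparison with wild type were the 10 largest rises and 10 largest falls among called genes for which both arrays lay beyond both wild-type arrays. In the other contrasts they were the 5 largest rises and falls. With fewer than 5 calls, the 5 smallest p-values were added. Up to 4 called members of each described list were named, or up to 2 with the smallest p where none was called. Lin28a was always reported, and Y-linked, X-inactivation, glycolysis, one-carbon and let-7 target genes could be named without a call.

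The analysis was repeated with quantile normalization, no detection filter, detection p below 0.01 in every group, each probe on its own, a variance trend with robust fitting, only the compared groups in the fit, a 1.5-fold minimum and leaving out each array. The series value table, planned as an alternative to neqc, became the main input. Slide as a block was not run because the tables used here name no slides. Chosen after seeing the data were removal of each array's background, the unnormalized signals, the run of title numbers as a block, the fit without the arrays numbered 20 to 22, and the mean of the fibroblast list as a covariate. The runs were examined because deviations from group means correlated across genes between arrays numbered 16 to 18, at 0.29 (labelled Lin28a loss and Lin28b loss), 0.54 (labelled Lin28a loss and double loss) and 0.69 (Lin28b loss and double loss). The labels do not say what the numbers stand for. Wild type lay in neither run, and the run as a block was applied only among the other groups. Comparisons with wild type and the interaction therefore ignore the runs. In them a shift tied to the runs cannot be told apart from a loss.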

Results

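LIN28A and LIN28B are RNA-binding proteins that block maturation of let-7 microRNAs. The series compared embryonic stem cells labelled as losing either gene or both with floxed wild-type cells, and its title names stem cell metabolism among its subjects. The cells were grown in serum with leukaemia inhibitory factor, and total RNA was profiled on 8 arrays, 2 per group. Across genes, the 2 wild-type arrays correlated at 0.9941, those labelled Lin28a loss at 0.9740, Lin28b loss at 0.9731 and double loss at 0.9642. The SD of the log2 difference between partners was 0.24 in wild type and 0.53, 0.54 and 0.62 in the other groups, so wild type was the tightest group.

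Lin28a itself was read by 2 probes, at 133559972 to 133560021 and 133559248 to 133559297 of chromosome 4 in the file's coordinates, whose build is not given in the sources used here. The brighter probe had an intensity of 601 ± 37 (SD, n = 2) in wild type, 468 ± 249 (SD, n = 2) in arrays labelled Lin28a loss, 701 ± 125 (SD, n = 2) in Lin28b loss and 104 ± 51 (SD, n = 2) in double loss. In double loss Lin28a fell by 2.43 on the log2 scale against wild type (SE 0.41, adjusted p = 0.0305). In the arrays labelled Lin28a loss the change was -0.45 (SE 0.41, adjusted p = 0.753), with intensities of 643.5 in replicate 1 and 291.9 in replicate 2. The other probe gave -2.91 in double loss and -0.59 in arrays labelled Lin28a loss. The call in double loss was lost without wild type replicate 1 or 2 (adjusted p = 0.309 and 0.244) and without double loss replicate 2 (adjusted p = 0.128), and without labelled Lin28a loss replicate 2 the change in arrays labelled Lin28a loss was 0.10. The target check therefore did not bear out that label but could not exclude it, since an interval of 2 SE ran from -1.26 to 0.36. These arrays, titled "flox" like wild type, are called "labelled Lin28a loss" throughout. Whether the deletion removes the probed part is not given in the sources used here. No Lin28b probe was among those analysed here, so loss of Lin28b could not be checked.

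**Figure D1:**
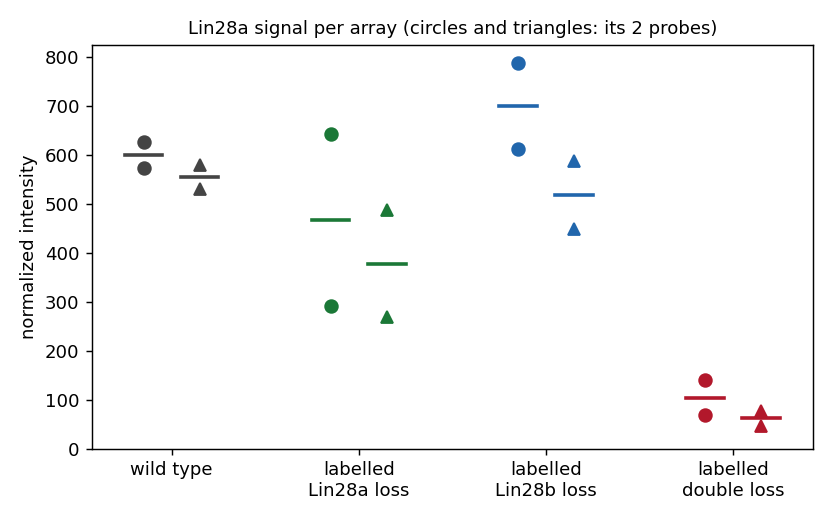
Normalized intensity of the 2 Lin28a probes (circles and triangles) on each array, by labelled group, with horizontal lines at group means. The brighter probe read 140.2 and 67.9 in double loss, and 643.5 and 291.9 in arrays labelled Lin28a loss against 627.4 and 574.6 in wild type.

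In arrays labelled Lin28a loss, the mitochondrial import receptor subunit Tomm22 was 4.03 higher than in wild type on the log2 scale (SE 0.34, adjusted p = 0.00155, n = 2 per group), and the ubiquitin-like modifier Ubd was at least 16.7-fold higher (adjusted p = 0.001). Other large rises were Ttc27 (3.45), Wdr46 (3.44), the epidermal genes Krtdap (at least 9.2-fold) and Lor (2.90), Abhd16a (2.92), Ms4a10 (2.86), Samd9l (2.84) and the immunoproteasome subunit Psmb9 (2.78). The probe used for the lysosomal protease Ctsc was at least 17.0-fold lower (adjusted p = 0.001, with -2.39 and -2.94 for its other probes), and Calml4 (-3.39), 2210409E12Rik (-3.19), the ubiquitin ligase Mid1 (-3.18), the matrix protein Mgp (-3.10), Olfr985 (-2.60), Foxq1 (-2.29) and Timmdc1 (-2.27) were lower too, with Arv1 at least 4.9-fold lower. A further Mid1 probe gave -1.71. The endoderm transcription factor Gata6 fell by 2.42 (SE 0.42, adjusted p = 0.0403). In all, 55 genes were higher and 40 lower. Since Lin28a was not reduced as in double loss, no direction here is ascribed to its loss.

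Primitive endoderm genes were lower as a group in these arrays. Of 20 measured, 2 fell (Gata6, and the endocytic adaptor Dab2 by 1.96), 0 rose and 18 were not called, while 9 fell when adjusted over the list alone. The list passed camera (median -0.72, adjusted p = 5.32e-06) but not with an estimated correlation (adjusted p = 0.545). Hypoxia and HIF targets had a median of 0.53 (adjusted p = 6.82e-06, and adjusted p = 0.545 with an estimated correlation) with 0 of 21 called, and 6 rose when adjusted over the list alone. The values of Ddit4 and Adm were 1.15 and 1.46. The hypoxia list also passed camera in Lin28b loss (median 0.45, adjusted p = 3.90e-06) and in double loss (median 0.54, adjusted p = 8.57e-04). With an estimated correlation the adjusted p there was 0.312 and 0.477. For interferon response the median was 0.67 (adjusted p = 6.57e-04, and 0.908 as the adjusted p with an estimated correlation), and Psmb9 was the 1 called member of 20. The primed epiblast list had a median of 0.36 (adjusted p = 0.0186, and adjusted p = 0.898 with an estimated correlation). Integrated stress response genes had a median of -0.31 (adjusted p = 0.0401, and adjusted p = 0.978 with an estimated correlation), and the cystine transporter Slc7a11 fell by 1.45. The mean of the stress list was -0.12 in replicate 1 and -0.51 in replicate 2. Fibroblast and feeder genes had a median of 0.46 (adjusted p = 0.00525, and adjusted p = 0.978 with an estimated correlation), with 0 of 22 called and a mean of 0.19 above wild type in replicate 1 and 1.06 in replicate 2. Quantile normalization called 143 genes (79 higher, 64 lower), and unnormalized signals, chosen after seeing the data, 66 higher and 74 lower. Leaving out wild type replicate 1 or 2 left 8 or 7 calls, and leaving out labelled Lin28a loss replicate 1 or 2 left 20 or 14.

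Lin28b loss gave fewer calls, 5 genes higher and 6 lower than wild type. The growth factor Fgf5, a marker of primed epiblast, rose by 2.83 (SE 0.31, adjusted p = 0.0181, n = 2 per group), the interferon-inducible gene Ifi27 by 2.76, the keratin Krt19 by 2.54, Lor by 2.48 and the lactate exporter Slc16a3 by 1.79. Mgp fell by 3.11 (SE 0.26, adjusted p = 0.0106), Lrrc34 by 2.07, the G protein subunit Gna14 by 1.88 and the circadian transcription factor Dbp by 1.85. Nostrin was at least 2.1-fold lower and the imprinted gene Mest, by the probe used, at least 3.2-fold lower. Other Mest probes gave -1.67 and -0.89, and a second Slc16a3 probe gave -0.45. Mgp had means of 9.32 in wild type, 6.21 in labelled Lin28a loss, 6.20 in Lin28b loss and 6.39 in double loss. Lor stood at 6.54, 9.44, 9.02 and 9.10 in that order. For such genes a shift of wild type against all other groups cannot be told apart from loss of Lin28b. Dbp (9.39 in labelled Lin28a loss, 9.54 in wild type) and Mest (8.24 and 6.64) were not lower in labelled Lin28a loss in this way.

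Trophoblast genes were higher as a group in Lin28b loss. Of 17 measured, 15 had positive values, Krt19 was called, and 8 rose when adjusted over the list alone (median 0.83, camera adjusted p = 9.86e-09). With an estimated correlation the adjusted p was 0.312. The interferon response list had a median of 0.93 (adjusted p = 1.54e-08, and adjusted p = 0.312 with an estimated correlation) with 0 of 20 called and 7 higher when adjusted over the list alone. Primed epiblast genes had a median of 0.67 (adjusted p = 1.99e-05, and adjusted p = 0.312 with an estimated correlation), and Fgf5 was the 1 called member of 15. Primitive endoderm genes had a median of -0.72 (adjusted p = 5.05e-04, and adjusted p = 0.312 with an estimated correlation) with 0 of 20 called and 10 lower when adjusted over the list alone. Naive pluripotency genes had a median of -0.40 (adjusted p = 9.43e-04, and adjusted p = 0.533 with an estimated correlation), with 0 of 18 called. Their means were -0.28 and -0.77 in replicates 1 and 2. Primitive streak and mesoderm genes had a median of 1.01 (adjusted p = 1.15e-04, and adjusted p = 0.501 with an estimated correlation) with 0 of 19 called, and means of 0.52 and 1.54 in replicates 1 and 2. Beside these, fibroblast and feeder genes lay 0.66 and 1.39 above wild type in replicates 1 and 2 (median 0.74, adjusted p = 5.64e-08, and adjusted p = 0.533 with an estimated correlation). With background removed the split was 23 higher and 10 lower, and with unnormalized signals 112 and 25, both chosen after seeing the data. Calls numbered 0 without either wild-type array, without either array labelled Lin28a loss and without Lin28b loss replicate 2, and 1 without Lin28b loss replicate 1, by limma. In the full fit 1520 genes had an unadjusted p below 0.05, against 1265 in arrays labelled Lin28a loss, so by this measure the order was the other way.

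Double loss differed from wild type in 150 genes, 77 higher and 73 lower. Some naive pluripotency factors were lower. Tcl1, a co-activator of AKT, fell by 2.43 (SE 0.27, adjusted p = 0.00478, n = 2 per group), Zfp42 by 1.99, Esrrb by 1.80 and Nr5a2 by 1.68. Of 18 naive pluripotency genes these 4 fell, 0 rose and 14 were not called, with a median of -0.75 (camera adjusted p = 2.45e-06, and adjusted p = 0.477 with an estimated correlation). In the trophoblast list Krt19 rose by 2.36, the placental gene Plac1 by 1.79, Krt8 by 1.59 and Krt7 by 1.24. These 4 of 17 were called, and 13 rose and 1 fell when adjusted over the list alone (median 1.05, camera adjusted p = 2.42e-06, and adjusted p = 0.477 with an estimated correlation). Other Nr5a2 probes gave -0.37 and -0.75. With the fibroblast covariate described below, Zfp42, Esrrb and Nr5a2 lost their call.

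The largest rises in double loss were Tomm22 (3.88), the acute-phase gene Saa3 (3.57), Wdr46 (3.32), Ttc27 (3.09), Ubd (at least 7.8-fold), Psmb9 (3.03), the collagen-crosslinking enzyme Lox (2.91), Fgf5 (2.78), Abhd16a (2.75) and Tmem87a (2.74). The largest falls were Ctsc (-3.88, other probes -2.22 and -2.86), 2210409E12Rik (-3.80), the dynein Dnah8 (-2.94), Olfr985 (-2.93), Mgp (-2.92), Mid1 (-2.80), Lrrc34 (-2.77), AA467197 (-2.73), LOC217066 (-2.70) and the transcription factor Msc (-2.54). A further Mid1 probe gave -1.24. Tomm22, Wdr46, Ttc27, Ubd, Psmb9, Abhd16a, Tmem87a, Ctsc and Mid1 lay apart from wild type in labelled Lin28a loss too, with Lin28b loss nearer wild type. Tomm22 had means of 11.72, 7.45 and 11.57 in labelled Lin28a loss, Lin28b loss and double loss. For these genes a difference between lines titled "ab" and "b" cannot be told apart from loss of both genes. Saa3, Lox, Fgf5, Mgp and Lrrc34 lay apart from wild type in Lin28b loss as well. With each array's background removed, an alternative chosen after seeing the data, the split was 203 higher and 92 lower, all 150 kept their call and direction, and the median change of all genes moved from -0.03 to 0.08. With unnormalized signals the split was 257 and 118.

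Fibroblast and feeder genes were higher in double loss, with positive values for all 22 members and a median of 1.33 (camera adjusted p = 1.68e-10, and adjusted p = 0.498 with an estimated correlation). Lox and the matricellular gene Ccn2 (1.30) were the 2 called, and 15 rose when adjusted over the list alone. The list mean lay 0.84 above wild type in replicate 1 and 2.11 in replicate 2. Interferon response genes had a median of 0.88 (adjusted p = 2.45e-06, and adjusted p = 0.477 with an estimated correlation), and Psmb9 was the 1 called of 20. The p53 target list had a median of 0.39 (adjusted p = 0.00146, and adjusted p = 0.477 with an estimated correlation), with Sfn 1.90 higher. For primed epiblast genes the median was 0.46 (camera adjusted p = 0.00592, and adjusted p = 0.477 with an estimated correlation). Primitive streak and mesoderm genes had a median of 0.95 (adjusted p = 0.0305, and adjusted p = 0.581 with an estimated correlation) with 0 of 19 called, and a mean of 0.07 in replicate 1 against 1.44 in replicate 2. With the fibroblast list mean as a covariate, chosen after seeing the data, Zfp42, Esrrb, Nr5a2, Krt8, Krt7, Lox, Ccn2, Saa3, Msc, LOC217066, Sfn and Lin28a were no longer called. For some the change shrank, as for Zfp42 (from -1.99, SE 0.35, to -1.06, SE 0.33), Esrrb (to -1.02), Krt8 (to 1.02), Saa3 (to 1.26), Lin28a (to -1.5) and Lox (to 1.01), itself a list member. For others the change held while the SE grew, as for Krt7 (from 1.24, SE 0.24, to 1.37, SE 0.34), Sfn (to 2.01, SE from 0.31 to 0.45) and Ccn2 (to 1.27, SE from 0.23 to 0.32). Calls numbered 10 and 0 without wild type replicate 1 and 2, 490 and 45 without double loss replicate 1 and 2, and 78 and 79 without labelled Lin28a loss replicate 1 and 2.

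**Figure D2:**
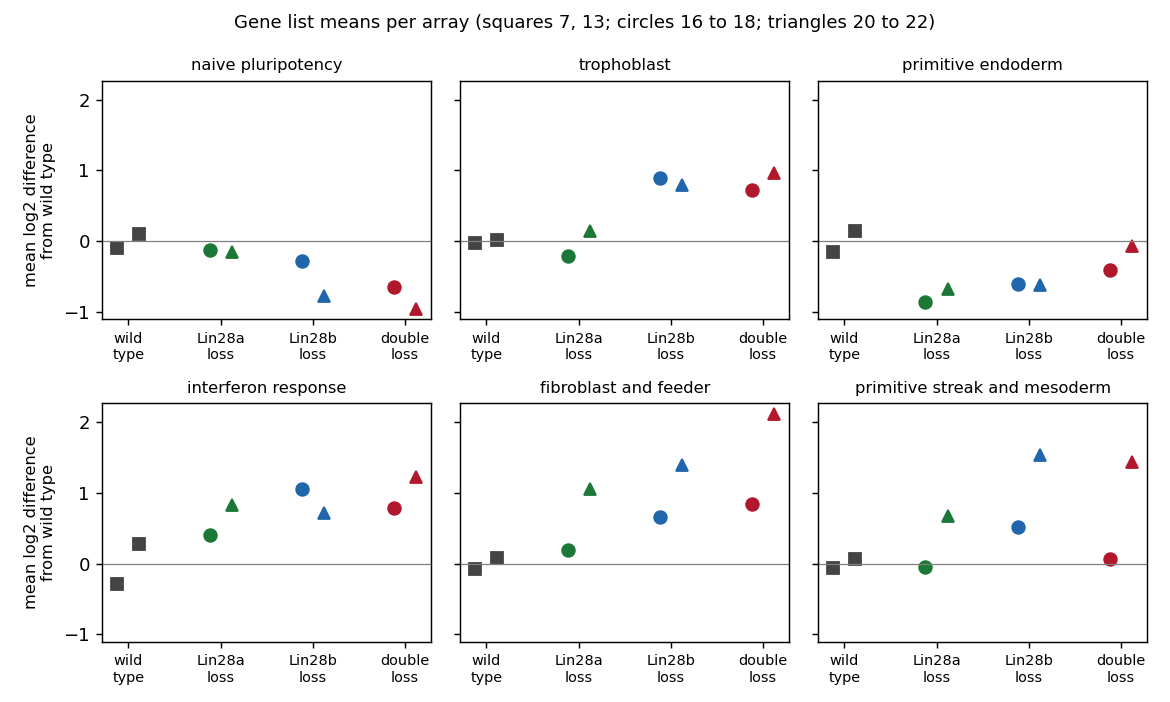
Mean log2 difference from the wild-type mean over the genes of 6 lists (vertical axes) for each array, by labelled group, with squares for arrays numbered 7 and 13, circles for 16 to 18 and triangles for 20 to 22. Trophoblast means lie at 0.89 and 0.79 in Lin28b loss and 0.72 and 0.97 in double loss, and fibroblast means are higher in the triangle than in the circle of each group.

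Few metabolic genes were called. In the glycolysis list 0 of 21 genes were called in arrays labelled Lin28a loss, 1 in Lin28b loss (Slc16a3, whose other probe gave -0.45) and 0 in double loss, with medians of 0.60, 0.26 and 0.31. Camera gave adjusted p = 1.54e-05, 7.86e-04 and 0.0432, and with an estimated correlation adjusted p = 0.849, 0.533 and 0.581. One-carbon and serine genes had medians of -0.16, -0.27 and -0.25 in the same order and passed in none of the 3 comparisons (adjusted p = 0.178, 0.159 and 0.0763), though Tdh, the threonine dehydrogenase of mouse stem cells, fell by 1.63 in double loss (SE 0.26, adjusted p = 0.0244). Phgdh, the first enzyme of serine synthesis, had values of -0.16, 0.04 and -0.24. Nuclear-encoded oxidative phosphorylation genes had medians of 0.08, -0.15 and -0.11, with 0 of 71 called in each (adjusted p = 0.405, 0.255 and 0.107). Targets of let-7, which LIN28 proteins would shield, had medians of -0.01, -0.02 and -0.06 with 0 of 40 called in each (adjusted p = 0.849, 0.243 and 0.649), though 3 rose in double loss when adjusted over the list alone. Their means, at 0.04, 0.08 and 0.11, and the direction camera gave were positive where the medians were negative. Hmga2 stood at -0.34, -0.07 and 0.48 and Igf2bp1 at -0.04, 0.03 and -0.19, each with an SE of 0.37 and 0.24.

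Arrays labelled Lin28a loss differed from Lin28b loss in 40 genes, 25 higher and 15 lower. Ubd was at least 23.7-fold higher in the former (adjusted p = 2.98e-04), and Tomm22 (4.26), Wdr46 (4.19) and Ttc27 (4.12) were higher, as was Mest by at least 9.6-fold by the probe used (2.50 and 1.91 for the others). Ctsc was at least 11.3-fold lower by the probe used (-1.97 and -2.42 for the others), Arv1 at least 5.0-fold lower, and Mid1 (-2.86, other probe -1.09), Calml4 (-2.79) and Mfap1b (-2.49) were lower. Lin28a differed by -0.66 (SE 0.41, adjusted p = 0.87). Among 17 trophoblast genes 3 were lower (Krt7 by -1.57, Plac1 by -1.56, and Hand1 at least 1.7-fold), 0 higher and 14 not called, with 8 lower when adjusted over the list alone (median -0.78, camera adjusted p = 3.56e-13, and adjusted p = 0.178 with an estimated correlation). Psmb9 was higher (2.73) and Psmb8 lower (-1.72). Fibroblast genes had a median of -0.40 (adjusted p = 0.00158, and adjusted p = 0.85 with an estimated correlation). Unnormalized signals, chosen after seeing the data, gave 24 higher and 40 lower. All 40 calls kept their direction within arrays 16 to 18 and within 20 to 22. Calling from these same arrays made that likely in advance, so it says little about the runs. The run as a block, chosen after seeing the data, called 260 genes. Within the runs the trophoblast median was -1.08 and -0.61 (blocked adjusted p = 9.58e-12). Calls numbered 16 without either wild-type array, 10 and 12 without labelled Lin28a loss replicate 1 and 2, and 16 and 14 without Lin28b loss replicate 1 and 2.

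Between double loss and the arrays labelled Lin28a loss, 1 gene was called. The zinc finger gene Zfp786 was at least 4.5-fold lower in double loss (adjusted p = 0.0118, n = 2 per group), and its other probe gave -1.27. Not passing were the neuropeptide precursor Trh (-2.36, adjusted p = 0.0563), Plac1 (1.99), Tcl1 (-2.21) and Gdf3 (-1.94), each with adjusted p = 0.058. Lin28a stood at -1.98 (adjusted p = 0.251, and adjusted p = 0.013 with the run as a block). The trophoblast list had a median of 1.07 (camera adjusted p = 1.42e-10, and adjusted p = 0.262 with an estimated correlation), with 0 of 17 called and 9 higher when adjusted over the list alone. Naive pluripotency genes had a median of -0.57 (adjusted p = 6.72e-08, and adjusted p = 0.487 with an estimated correlation). Fibroblast genes had a median of 0.92 (adjusted p = 2.52e-08, and adjusted p = 0.601 with an estimated correlation). Within arrays 16 to 18 and 20 to 22 the trophoblast median was 1.18 and 1.14, the naive pluripotency median -0.54 and -0.84 and the fibroblast median 0.70 and 1.08. With the run as a block 373 genes were called. Calls numbered 0 without either wild-type array, without either array labelled Lin28a loss or without double loss replicate 2, and 2 without either Lin28b loss array, while 885 genes had an unadjusted p below 0.05 in the full fit.

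Double loss against Lin28b loss gave 28 calls, 19 higher and 9 lower. Tomm22 (4.12), Wdr46 (4.06), Ttc27 (3.76), Psmb9 (2.97) and Ubd (at least 11.1-fold) were the largest rises. Ctsc (-3.28, other probes -1.80 and -2.33), Lin28a (-2.64, adjusted p = 0.0474), Mid1 (-2.48), Dnah8 (-2.28) and the clathrin adaptor Picalm (-2.14) were the largest falls, and another Mid1 probe gave -0.61. The call of Lin28a was lost with quantile normalization (adjusted p = 0.0809), without wild type replicate 1 or 2 (0.118 and 0.119), without Lin28b loss replicate 1 or 2 (0.211 and 0.353) and without double loss replicate 2 (0.186), with adjusted p from 5.53e-07 to 0.353 over all alternatives. Mitotic cell cycle genes had a median of -0.25 (camera adjusted p = 7.45e-05, and adjusted p = 0.908 with an estimated correlation) with 0 of 25 called. Its values for Plk1 and Ube2c were -1.07 and -1.11, and the list median was -0.09 within arrays 16 to 18 and -0.43 within 20 to 22. Fibroblast genes had a median of 0.47 (adjusted p = 0.0127, and adjusted p = 0.908 with an estimated correlation), a direction that turned without double loss replicate 2 (-0.14) or, in the camera test, without Lin28b loss replicate 1 (median 0.03). All 28 calls kept their direction within each run, which calling from the same arrays made likely in advance. The run as a block called 131 genes. Calls numbered 15 without either wild-type array, 11 and 15 without Lin28b loss replicate 1 and 2, and 15 without double loss replicate 1. The stricter detection filter called 18 genes, and unnormalized signals gave 16 higher and 16 lower. With only the compared groups in the fit 5 genes were called, 4 higher and 1 lower. The full fit also draws its spread from the wild-type pair, the tightest group.

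**Figure D3:**
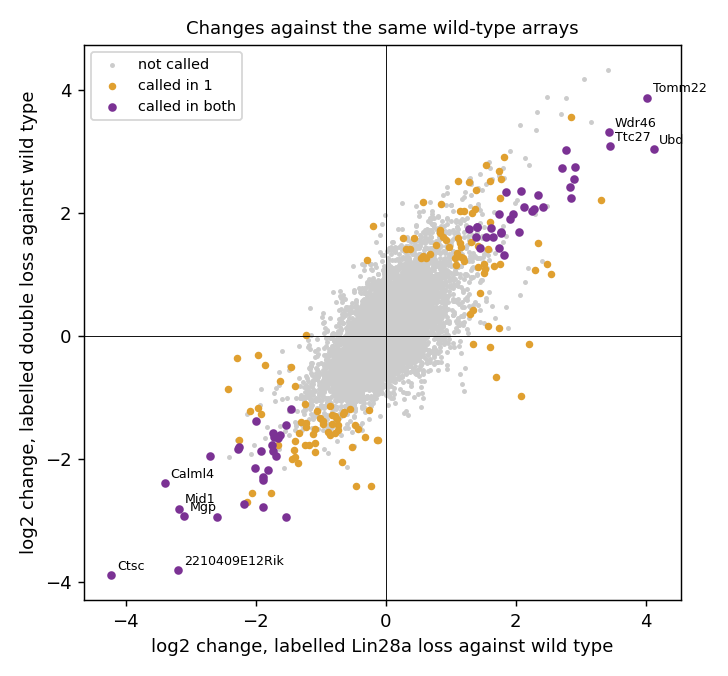
Log2 change from wild type of each tested gene in arrays labelled Lin28a loss (horizontal) and double loss (vertical), with genes called in 1 or both comparisons coloured. The 60 genes called in both lie in matching directions, 33 higher and 27 lower.

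The comparisons with wild type shared genes. Arrays labelled Lin28a loss and double loss shared 33 higher and 27 lower genes and 0 in opposite directions, where independent lists would share 0.372 and 0.257. Unchanged groups simulated against a shared pair of wild-type arrays, simulated as well, shared 0.02 on average over 100 simulations. With no change simulated hardly any gene can be called, so this is no baseline for lists as long as these. The changes covaried at 0.21 against 0.05 simulated (correlation across genes 0.72 against 0.50). Lin28b loss and double loss shared 4 higher and 3 lower genes, with a covariance of 0.24 (correlation 0.78), and arrays labelled Lin28a loss and Lin28b loss shared 3 higher and 4 lower and 1 opposite, with a covariance of 0.17 (correlation 0.67). With no wild-type array in common the covariances were 0.20 and 0.19, 0.23 and 0.22, and 0.15 and 0.16 in that order. Labelled Lin28a loss and double loss also share the title letters "ab". Tomm22, high in both, had a mean of 7.45 in Lin28b loss against 7.69 in wild type. A difference between the cell lines can therefore not be told apart in their overlap. Part of the overlap may still come from the shared wild-type arrays, though the covariances were little lower with none in common. The simulation gave wild type the spread of all groups, while its SD of the difference between partners was 0.24 against 0.53 to 0.62 elsewhere. Its 0.05 may thus overstate what a shared wild type brings. It left out the runs of title numbers, which the other groups share and wild type does not. With them the covariance with no effect could lie above 0.05, so 0.05 is no firm baseline.

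The interaction asked whether double loss differed from the sum of the separate losses, and 1 gene passed. Nostrin, a regulator of endothelial nitric oxide synthase, had an interaction of 3.25 (SE 0.33, adjusted p = 0.0482). Its means were 6.02 in wild type, 4.16 and 4.15 in labelled Lin28a loss and Lin28b loss and 5.55 in double loss. Neither group labelled as a single loss lay above background, so 3.25 is not exact. With both held at the lowest level detected in their group, a test chosen after seeing the data, the interaction was 1.43. Not passing were Mgp (3.29), Lor (-2.83), Trh (-3.05) and Ptpn6 (-2.85), each with adjusted p = 0.0527. Lin28a had -2.18 (adjusted p = 0.489). Primitive endoderm genes had a median interaction of 1.14 (camera adjusted p = 3.60e-08, and adjusted p = 0.369 with an estimated correlation), with positive values in 18 of 20, 0 called and 6 higher when adjusted over the list alone. Dab2 and Sox17 stood at 2.82 and 2.16. Glycolysis genes had a median of -0.50 (adjusted p = 2.72e-06, and adjusted p = 0.542 with an estimated correlation), with Slc16a3 at -2.03 and its other probe at 0.80. Because the arrays labelled Lin28a loss enter this contrast, its directions rest on that label. A shift shared by all groups other than wild type would enter it with the opposite sign and cannot be told apart from an interaction. Mgp changed by -3.10, -3.11 and -2.92 against wild type in labelled Lin28a loss, Lin28b loss and double loss. Trh and Ptpn6 did not shift alike, with means of 11.92 and 9.23 in double loss against 12.58 and 9.06 in wild type. Quantile normalization called 0 genes, 8 were called without double loss replicate 1, and 0 were called without any other array, with 810 genes at an unadjusted p below 0.05 in the full fit.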

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

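The unnormalized signals and the test at the bounds were chosen after the data were examined. Nostrin was singled out because its change in double loss differed from the sum of the separate changes (interaction 3.25, limma adjusted p = 0.0482). Neither single-loss group as labelled lay above background for this gene (detection p = 0.853 in labelled Lin28a loss and 0.749 in Lin28b loss), so 3.25 rests on levels that were not measured exactly, and with both held at the lowest level detected in their group it was 1.43. The value was 2.76 with quantile normalization (adjusted p = 0.0511) and 2.87 with unnormalized signals (adjusted p = 0.0502), and its adjusted p ran from 2.41e-07 to 0.408 over all alternatives.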

How the results depend on the processing

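The removal of background, unnormalized signals, run block, fibroblast covariate and fit without the arrays numbered 20 to 22 were chosen after the data were examined, and the cause of the shifts was not tested unless stated. Comparisons are given as labelled Lin28a loss, Lin28b loss and double loss for those with wild type. Quantile normalization called 143 genes in labelled Lin28a loss, 6 in double loss against labelled Lin28a loss and 0 for the interaction. With only the compared groups in the fit, 145 were called in labelled Lin28a loss, 65 in double loss, 0 in double loss against labelled Lin28a loss and 5 in double loss against Lin28b loss. With background removed the counts were 173, 33 and 295 against wild type, 6 in double loss against labelled Lin28a loss and 12 for the interaction. Unnormalized signals gave 137 in Lin28b loss, 375 in double loss, 64 in labelled Lin28a loss against Lin28b loss, 9 in double loss against labelled Lin28a loss and 12 for the interaction. A variance trend with robust fitting gave 23 in Lin28b loss, 5 in double loss against labelled Lin28a loss and 7 for the interaction. Each probe on its own gave 64 in labelled Lin28a loss against Lin28b loss and 4 in double loss against labelled Lin28a loss. No detection filter gave 4 there and 7 for the interaction. The stricter filter gave 0 there, 18 in double loss against Lin28b loss, 5 for the interaction, and overlaps of 13 (labelled Lin28a loss with Lin28b loss) and 12 (Lin28b loss with double loss). The covariate gave 454, 82 and 186 against wild type, 176, 31 and 105 in labelled Lin28a loss against Lin28b loss, double loss against labelled Lin28a loss and double loss against Lin28b loss, and 87 for the interaction. The run block gave 260, 373 and 131 in those 3 contrasts.

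Without the arrays numbered 20 to 22 the counts were 2357, 1295 and 2089 against wild type, 1125, 1159 and 320 among the groups other than wild type and 682 for the interaction. Only the wild-type pair, the closest, then sets the spread, so these counts are not comparable. There Lin28a was 0.10 in labelled Lin28a loss against wild type and 0.07 against Lin28b loss, and the oxidative phosphorylation list had a median of -0.14 against Lin28b loss. On all arrays that median was 0.24, with 65 of 71 genes positive (camera adjusted p = 0.00625, and adjusted p = 0.864 with an estimated correlation). Leaving out each array gave 7 to 117 calls in labelled Lin28a loss, 0 to 14 in Lin28b loss, 0 to 490 in double loss, 10 to 59 in labelled Lin28a loss against Lin28b loss, 0 to 2 in double loss against labelled Lin28a loss, 11 to 24 in double loss against Lin28b loss, 0 to 8 for the interaction and 58 to 80 list shifts, where the lone array is assumed to vary like the others. Over the arrays left out, medians in double loss against labelled Lin28a loss ran from -0.51 to 0.10 for mitotic (-0.19 on all arrays) and from -0.34 to 1.34 for primitive streak genes (0.43 on all arrays), turning without double loss replicate 2. In double loss against Lin28b loss they ran from -0.14 to 1.16 for fibroblast (0.47 on all arrays) and from -0.43 to 0.27 for general pluripotency genes (-0.02 on all arrays). There both turned without double loss replicate 2 (-0.14 and 0.18), the pluripotency median also turned without Lin28b loss replicate 1 (0.27), and the camera direction for fibroblast genes turned without Lin28b loss replicate 1 (median 0.03). Lin28a in labelled Lin28a loss ran from -1.0 to 0.10, turning without labelled Lin28a loss replicate 2. List shifts numbered 0 with an estimated correlation and with fry. With no shared wild-type array, overlaps were 6 and 0 for labelled Lin28a loss with double loss and 0 for the other pairs. The 6 were shared in direction by fits of 7 and 10 calls, while in each overlap of 0 a fit made 0 calls, so those say nothing. The 1.5-fold minimum left the counts unchanged. Slide as a block and neqc were not run. Dim genes are limited by signal close to background.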

Other observations

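The tests of chromosome neighbours, of Lin28a, of fibroblast and primitive streak genes between runs and of background level were chosen after the results were seen. The predictions for further probes and for the fibroblast covariate were written before theirs, though the covariate itself was added after the data were examined. Genes named for the differences between runs, and Zscan4c, were chosen after their values were seen. Genes of the 2-cell-like state, a rare embryonic program of stem cells, had medians of 0.98 in Lin28b loss (camera adjusted p = 0.00595, and adjusted p = 0.65 with an estimated correlation) and 1.09 in double loss (adjusted p = 0.0136, and adjusted p = 0.581 with an estimated correlation), with 0 of 8 called in either. The list mean of 8 genes lay 1.34 and 0.30 above wild type in Lin28b loss replicates 1 and 2 and 1.77 and 0.28 in double loss, so it stood highest in the arrays numbered 16 and 17. Zscan4c had a value of 2.16 in double loss (adjusted p = 0.17). The Y-linked genes Ddx3y and Eif2s3y were read in all groups, with Eif2s3y at a log2 of 7.06 and 7.98 in double loss against 9.08 and 9.01 in wild type.

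Several large differences separated arrays titled "ab" from those titled "b" rather than losses from wild type, such as Ubd, Tomm22, Wdr46, Ttc27, Psmb9, Ctsc and Mid1, and a candidate explanation is that the cell lines carry differing chromosome segments. Among the 100 smallest p-values between arrays labelled Lin28a loss and Lin28b loss, 38 genes had another within 5 tested genes, against 8.43 on average and 26 at most over 10000 random draws (permutation p = 1.00e-04). Between double loss and Lin28b loss 18 did (permutation p = 0.0168) but only 2 of its 28 called genes (permutation p = 0.285), and chromosome 17, with 559 of 11377 tested genes, held 8 of 40 and 8 of 28 calls in the 2 comparisons, yet 25 did between double loss and labelled Lin28a loss, which share the title letters, and co-regulated neighbours count too, so segments stay open. A sequence variant under a probe would leave other probes still, yet 88.9% of 9 further probes moved alike. In 6 of the 7 genes with a further probe all of them did, which argues against such a variant for those genes, Mid1 being the exception. The other 33 of 40 genes had no further probe, so for them it cannot be told apart. Loss of Lin28a stays open as well, since its change of -0.45 in those arrays has an interval of 2 SE from -1.26 to 0.36 and the title letters follow that label.

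Arrays numbered 20 to 22 stood apart from 16 to 18 in all 3 groups other than wild type. Of 11377 genes, 43.2% had one sign of difference in all 3, where chance gives 25%. Some lists moved apart between groups. Of 63 cytosolic ribosomal protein genes, 60 were higher in labelled Lin28a loss, 3 in Lin28b loss and 5 in double loss. Of 71 oxidative phosphorylation genes, 57, 6 and 8 were higher in that order. The arrays of the runs thus did not differ alike in every group, as the run block assumes. Wild type, in neither run, had medians of 0.55 and 0.27 for these lists in replicate 2 over replicate 1. Both lists rose where the slope of the deposited intensities rose (0.65 to 1.14 in wild type, 0.87 to 1.45 in labelled Lin28a loss). They fell where it fell (1.08 to 0.84 in Lin28b loss, 1.15 to 0.90 in double loss). Their shifts can therefore not be ascribed to the runs. Fibroblast genes such as Dcn, Mmp3 and Col1a1 were higher, with at least 86.4% of 22 list members higher in every group, which is consistent with a larger share of fibroblasts, a hypothesis not excluded by Vim (1.08 higher) or Acta2 (1.01 higher), though 21 of the 22 lay above background in wild type. That share does not account for primitive streak genes, whose median was 0.93 higher and within 0.28, the SE of the difference, of the fibroblast median, with T 3.46 higher and Mixl1 2.27 higher, values fibroblasts would not bring. Another state of the cultures could underlie this part and was not tested. The stress genes Chac1 and Trib3 were lower in all 3 groups, with differences of -1.91 and -1.48 or lower.

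The 150 calls of double loss against wild type might stem from more fibroblast RNA in double loss. With the fibroblast mean as a covariate their median size was 85.3% of that without, from 1.76 to 1.5, all 150 kept their sign, the median SE rose from 0.27 to 0.34, and 54 stayed called among the 186 calls then made. The prediction for fibroblasts as the cause was therefore not met. Yet the covariate's slope comes only from differences between the 2 arrays of a group, which are small where genes are called. A kept size was thus likely in advance, and fibroblasts stay open as a cause. Lox stood at 1.01 with the covariate and 2.91 without, and Zfp42 at -1.06 and -1.99. Background left in the arrays is argued against for these genes, since 100.0% stayed called with it removed.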
